A study of Mus musculus with 6 samples.

How the data were processed

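Messenger RNA was measured in 6 libraries of cultured mouse OT-I T cells, 3 control and 3 with acetate, made with a stranded mRNA kit per the labels' protocols. The deposited files hold raw read counts per gene symbol, 1 library per file. STAR 2.4.0h, HTSeq and DESeq2 1.6.3 and the genome build mm10 are named per the submitters' processing notes, with no role or order. The annotation, the strand setting and the version of the counting tool are not given in the sources used here. Antisense and overlapping genes are therefore not singled out, and genes with near-identical copies, such as histone and ribosomal protein genes, have uncertain counts. Each deposited file ends in 5 rows that name no gene. They held 7.53 to 9.83% of all counted rows as reads in no gene, 0.478 to 0.579% as ambiguous reads and 35.0 to 39.9% as reads that aligned to several places. These rows stayed out of library sizes and tests.

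Groups were taken from the sample titles. Library totals over genes were 99.4 M (control 1), 86.6 (acetate 2), 76.9 (control 3), 74.6 (acetate 4), 72.0 (control 5) and 78.4 M (acetate 6). At this depth counting error is small beside the spread between libraries for all but the lowest genes. Replicate libraries of a group were checked for duplication with a chi-square statistic of their counts, which was 82.5 to 201 per degree of freedom. No 2 libraries of the same group thus agreed within sampling noise. Control libraries were not checked against acetate libraries in this way.

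Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr with its defaults (12156 genes), scaled by TMM, and tested with the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. The design compares 3 acetate with 3 control libraries without pairs. A fit with the replicate block (libraries 1 and 2, 3 and 4, 5 and 6) was an alternative. This design, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Titles number the libraries from 1 to 6 with control odd and acetate even, and the names the submitters gave their files hint at 3 sets; no label says that adjacent libraries were cultured or prepared together. Deviations from the group means correlated across genes at 0.736, 0.338 and 0.653 for the 3 adjacent pairs, all over the minimum of 0.1 set for pairing, and each library correlated best with its own neighbour. Of the 6 possible pairings, 1 would come out best by chance alone. By that check the adjacent libraries were taken as pairs before the calls of both fits were compared, and the paired values are given beside the others. The fits had 4 residual degrees of freedom without pairs and 2 with pairs, and a median of 7.45 and 15.6 in all once the spread was shared across genes.

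CPM values are TMM-scaled, log2 CPM values use a prior count of 2, errors of group means are SD over 3 libraries, and the standard error of a log2 change is its size divided by the square root of the F statistic. Of 38 gene lists fixed in this way 35 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera with an estimated correlation and fry served as alternatives. With an estimated correlation camera works on the residual degrees of freedom, 4 without pairs and 2 with pairs. Its power is therefore low, most of all with pairs, and a list that it does not call is not thereby shown to owe its call to correlated members. Adjusted over the list alone means Benjamini-Hochberg adjustment within the members of 1 list. A list of mitochondrially encoded transcripts was not analysed here, since none of its 15 members was found among the symbols. Granulocyte and gamma-delta T cell markers had 2 and 3 tested members and were too few for a list test. In the paired fit Kit, a mast cell marker, was lower (log2 change -0.43), a call lost without control 3 and acetate 4 (adjusted p = 0.051), and Cd163l1 was higher (1.05).

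The rule for named genes took 24 key genes, genes past the threshold with groups apart (none without pairs), up to 4 members of each described list with the smallest p, and up to 5 genes per direction with the smallest unadjusted p. The part on genes past the threshold (the 10 largest changes at a mean CPM of at least 5 and the 5 smallest p per direction) was applied again to the paired fit, with the same direction in all 3 pairs in place of groups apart. That use was chosen after the values were seen. Some of the key genes are not reported here. Gene positions come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, in which 23902 of 24062 symbols matched 1 gene; transcript lengths come from GENCODE M21, for 23681 symbols. The length trend was a robust local regression of the paired log2 change on log2 length over genes outside the lists, centred on their median.

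The test was checked on simulated counts with the real library sizes and pair means, in 3 simulations with 200 changed genes each among 12056 to 12074 tested. For acetate against control the paired fit recovered 68.7% of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold changes, with at most 18 false calls in a simulation. The fit without pairs recovered 0%, 4% and 58.1% with 0 false calls. The simulated libraries shared pair means by construction, which favours the paired fit. A list raised 1.5-fold in simulation was called by camera in both fits. With an estimated correlation it was called without pairs (adjusted p = 0.00831) and missed in the paired fit (0.16). The simulated genes were drawn independently of each other. In the real libraries members of some lists correlated, with estimates of 0.69 for G1/S and 0.64 for G2/M genes in the paired fit. For other called lists the estimate lay near the preset, such as effector genes (-0.03) and natural killer cell markers (0.01). The simulation therefore cannot show how camera behaves with correlation as high as in the G1/S and G2/M lists.

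Alternatives covered the scaling (median-ratio factors, upper quartile, library totals), the filter (none, or at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, library quality weights, a fit that is not robust, a threshold of 0.1, a minimum fold of 1.2 (glmTreat) and leaving out each library. Most of them were repeated for the paired fit, leaving out each pair in place of each library, as alternatives chosen after seeing the data.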

Results

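RNA-seq read counts were analysed from 6 libraries of mouse OT-I cells, CD8+ T cells that carry a transgenic receptor for an ovalbumin peptide. Per the labels, OVA-specific memory cells of C57BL/6 lymph node origin were activated with 1e-09 M peptide and splenocytes for 3 days and then kept in IL-15 at 10 ng/mL for 3 to 4 days without peptide. The cells of libraries 2, 4 and 6 also received acetate at 5 mM over the final 3 days. The 3 control libraries are numbered 1, 3 and 5. Between 72.0 M and 99.4 M reads per library were counted in genes, and 14547 to 15181 of 24062 gene symbols had at least 1 count. The labels do not say whether the libraries came from separate cultures or animals. Without pairs the p-values measure the spread between these libraries, and with pairs the spread of the 3 differences within pairs. Either spread may be technical.

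The libraries parted by their number as well as by group. Principal component 1 (49.7% of the variance) ran from -38.3 for acetate 2 to 39.6 for control 5, and in each adjacent pair of numbers the acetate library lay lower than its control. On component 2 (27.9%) the controls lay between 8.09 and 28.9 and the acetate libraries between -28.6 and -0.61. Control 1 deviated from its group mean together with acetate 2 (correlation across genes 0.736), control 3 with acetate 4 (0.338) and control 5 with acetate 6 (0.653). Counts of changed genes are therefore given both without and with these 3 adjacent pairs as blocks, and the fit with blocks is called the paired fit below. Values for single genes and lists are from the paired fit unless said otherwise. Without pairs no gene passed edgeR's test with its default filter, though DESeq2 called 789. All tested lists but that of erythroid and platelet markers had the same camera call in both fits. The words rose, fell and changed are used only for genes with an adjusted p under 0.05 in the paired fit. Of all 12156 tested genes 2189 rose and 1782 fell in that fit, and member counts of lists stand against that background.

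**Figure D1:**
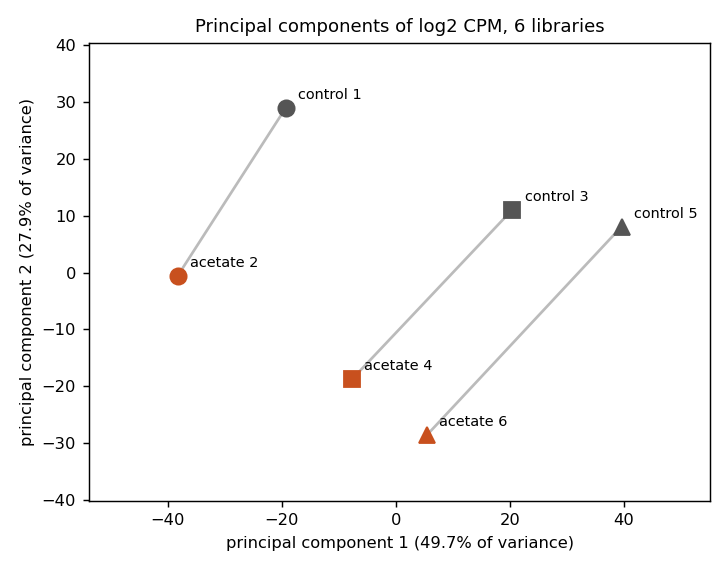
Principal components of log2 CPM (counts scaled to library size) over 12156 tested genes, with component 1 (49.7% of the variance) on the x axis and component 2 (27.9%) on the y axis. Each point is a library, grey for control and orange for acetate, and lines join adjacent title numbers; in all 3 pairs the acetate library lies lower on both components.

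The comparison of acetate with control asks which transcripts differ after 3 days of acetate in cultured memory CD8+ T cells. In the paired fit, genes of the cell cycle rose together: all 41 tested genes of DNA replication and G1/S and 40 of 42 genes of G2/M and mitosis, the latter by a median of 1.08 on the log2 scale. Of 28 tested cytotoxic and effector genes 17 rose, among them the granzyme gene Gzmb (2.49-fold), while the perforin gene Prf1 fell by 0.58 on the log2 scale. Of 27 memory and naive T cell genes 13 fell and 5 rose. The 2 acetyl-CoA synthetase genes Acss1 and Acss2, which activate acetate, fell by 0.38 each.

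Without pairs, edgeR's quasi-likelihood test called 0 of 12156 genes at an adjusted p of 0.05. The lowest adjusted p was 0.0702, and 1993 genes had an unadjusted p under 0.05, of which 1200 were higher in acetate. On the same libraries DESeq2 called 789 genes (547 higher, 242 lower) and limma-voom 0, with 2179 and 1994 genes at an unadjusted p under 0.05. The paired fit called 3971 genes, 2189 higher and 1782 lower, and 3944 of these moved in the same direction in all 3 pairs. With library totals as the only scaling it called 2304 higher and 1232 lower. Most changes were small: the median absolute log2 change of the called genes was 0.33, and 423 changed at least 2-fold, 387 of them upward. Groups did not overlap for 22.9% of the tested genes. The expected share is 10% for 3 libraries against 3 if all are exchangeable, which paired libraries are not. Genes also move together, and the share in other splits was not computed, so the difference from 10% is not a test. The pairing rests on adjacent numbers and on the correlations above, not on a statement in the labels, and without the pair of control 5 and acetate 6 the paired fit called 2484 genes.

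Among genes of at least 5 mean CPM, the largest increases were in S100a4 (3.06-fold), a calcium-binding protein of activated and effector lymphocytes, Gtf2ird1 (log2 change 1.56), Depdc1a (1.38), Cd72 (1.35), Slc9a5 (1.33), Clhc1 (1.33), Birc5 (1.33) and Gzmb (1.31). S100a4 (chromosome 3, 90603770 to 90606045 in GRCm38.p6) had 14.2 ± 8.82 CPM in control and 42.5 ± 24.8 CPM in acetate (SD, n = 3), with an adjusted p of 8.58e-08 in the paired fit and 0.209 without pairs. The largest decrease was in Syt6, a synaptotagmin (chromosome 3, 103575245 to 103645567), from 14.8 ± 3.00 to 3.73 ± 1.70 CPM (SD, n = 3; adjusted p = 1.01e-06 paired, 0.0814 without pairs). Sntb1 fell by 1.03, Tspan32 by 0.95, Nipa1 by 0.91 and Rundc3a by 0.81 on the log2 scale. Ranked by unadjusted p without pairs, Gtf2ird1, Palm, Tipin, Ifi30 and H1f0 led the genes with higher values, each at an adjusted p of 0.0702. Icam2, Scml4, Vipr1, Ppp1r13b and Jade2 led those with lower values, each at 0.0814. All 10 passed in the paired fit, the first 5 with log2 changes of 0.74 to 1.56 and the last 5 between -0.59 and -0.53.

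Cell cycle genes lay higher in acetate in all 3 pairs. For G1/S genes the mean log2 CPM rose by 0.53, 0.63 and 0.77 in the 3 pairs, and for G2/M genes by 0.87, 0.98 and 1.16. Rrm1, the large subunit of ribonucleotide reductase (chromosome 7, 102441695 to 102469771), went from 226 ± 34.2 to 395 ± 36.1 CPM (SD, n = 3; adjusted p = 5.31e-07 paired, 0.0814 without pairs). Dut rose by 0.65, Rfc5 by 0.60 and Gins1 by 0.85. Cdk1, the kinase that drives entry into mitosis (chromosome 10, 69335146 to 69352912), went from 43.6 ± 18.0 to 99.3 ± 23.6 CPM (SD, n = 3; adjusted p = 1.61e-05 paired, 0.126 without pairs). Cyclin A2 (Ccna2) rose 2.25-fold, Ccnf by 1.09, Ncapg by 1.01 and Nuf2 by 1.26 on the log2 scale. Adjusted over the list alone, 32 of 41 G1/S genes and 24 of 42 G2/M genes passed even without pairs, all of them higher, and 41 and 41 passed in the paired fit. The camera test with a preset correlation of 0.01 called both lists in both fits (adjusted p = 1.85e-17 and 9.03e-22 paired). With an estimated correlation neither was called, at an adjusted p = 0.690 for each in the paired fit and 0.474 and 0.644 without pairs. Fry called each list in only 1 of the fits. For G1/S its adjusted p was 0.0623 paired and 0.0375 without pairs, and for G2/M 0.0466 paired and 0.250 without pairs. The pairs differed as much as the groups: mean G2/M levels were 5.99 in control 1 and 5.94 in acetate 6.

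**Figure D2:**
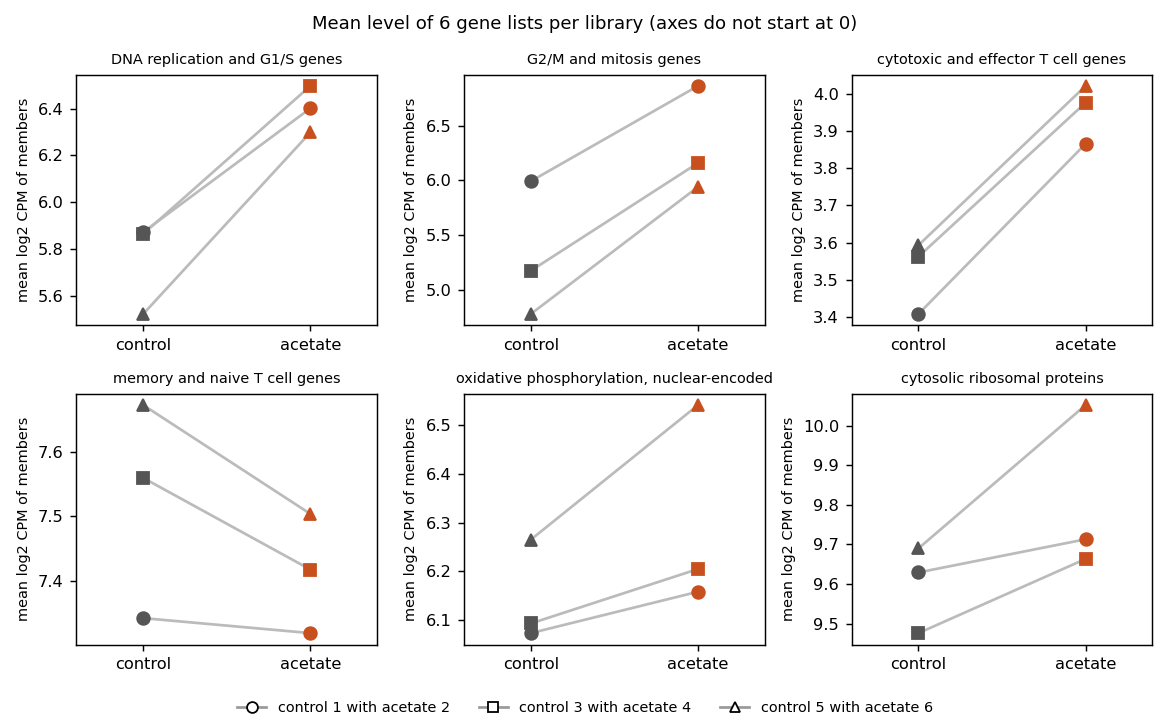
Mean log2 CPM of the tested members of 6 gene lists (y axis) in each library by group (x axis), grey for control and orange for acetate, with lines joining adjacent title numbers. G1/S and G2/M genes lie higher in acetate in all 3 pairs, with mean G2/M differences of 0.87, 0.98 and 1.16.

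Effector genes rose in part. Gzmb (chromosome 14, 56258836 to 56262334) went from 29.2 ± 11.2 to 72.1 ± 23 CPM (SD, n = 3), a log2 change of 1.31 with a standard error of 0.0971 and an adjusted p of 1.56e-05 in the paired fit and 0.131 without pairs. Tbx21, which encodes the transcription factor T-bet, rose by 0.48. The chemokine gene Xcl1 rose by 0.99, the receptor gene Il18rap by 0.69 and Il12rb2 by 0.44. Prf1 (chromosome 10, 61297751 to 61304684) went the other way, from 19.8 ± 2.46 to 13.2 ± 1.39 CPM (SD, n = 3; adjusted p = 4.36e-05 paired, 0.120 without pairs). Interferon-gamma (Ifng) lay at 0.268 CPM on average and Tnf at 5.53 CPM, with log2 changes of 0.63 and 0.77 that did not pass (adjusted p = 0.176 and 0.290 paired). Tnf differed by -0.19, 0.87 and 1.61 in the 3 pairs. It passed without control 1 and acetate 2 (adjusted p = 3.96e-05) and without control 3 and acetate 4 (0.000905). These fits rest on fewer libraries and a poorly known spread. In the second the pairs left went opposite ways (-0.19 and 1.61), so its p-value does not show a shared change. Il2 had 1 to 7 counts per library and was not tested. Of the 28 effector genes 17 rose and 2 fell, and the same numbers passed when adjusted over the list alone; without pairs 8 higher and 1 lower passed over the list alone. Camera called the list in both fits (adjusted p = 0.000159 paired), though not with an estimated correlation (adjusted p = 0.690 paired, 0.474 without pairs). Natural killer cell markers, 2 of which are also on this list, rose in 7 of 15 cases, with a median log2 change of 0.58 (camera adjusted p = 0.00389 paired, 0.690 with an estimated correlation). Most of these markers were at low levels, with a median of 0.634 CPM.

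Some receptor genes often grouped as inhibitory also rose. Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553), went from 4.10 ± 0.655 to 8.21 ± 1.08 CPM (SD, n = 3; adjusted p = 3.94e-06 paired, 0.0823 without pairs). Tigit rose by 0.67, Entpd1 by 1.32 and Cd244 by 1.36 on the log2 scale, the last 2 from low levels (means of 2.31 and 0.384 CPM). Cd244 is also on the list of natural killer cell markers, which was called higher (camera adjusted p = 0.00389 paired, 0.690 with an estimated correlation). In all 7 of 19 members rose and 1 fell, as also when adjusted over the list alone. The camera call was close to the threshold in the paired fit (adjusted p = 0.0497) and was lost without control 3 and acetate 4 (0.193) or control 1 and acetate 2 (0.0505); with an estimated correlation it was at an adjusted p = 0.690. Without pairs it was called at an adjusted p = 0.00969 (0.474 with an estimated correlation), though not without acetate 4 (0.0522). Tnfrsf9 (4-1BB), on the list of IL-2 and IL-15 targets, rose by 1.09, while that list as a whole was not called (4 of 23 members rose, 2 fell, or 2 and 2 adjusted over the list alone; adjusted p = 0.725 paired).

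Memory and naive genes fell more often than they rose. The integrin gene Itga4 (chromosome 2, 79255426 to 79333114) went from 629 ± 161 to 385 ± 41.0 CPM (SD, n = 3; adjusted p = 9.61e-05 paired, 0.144 without pairs). Lef1 fell by 0.39 and the IL-7 receptor gene Il7r by 0.41. Ly6c2, a surface antigen of memory and effector CD8+ T cells, rose by 1.12, and the transcription factor gene Eomes, which is also on the list of natural killer cell markers, by 0.39. Tcf7, the most abundant member at a mean of 1807 CPM, differed by -0.12 and Il2rb by -0.01, and neither passed. Over the list alone 13 fell and 5 rose, as over all genes. Camera called the list lower (adjusted p = 0.0177 paired, 0.0466 without pairs), with adjusted p = 0.690 and 0.765 with an estimated correlation, and the paired call was lost without control 5 and acetate 6 (0.0873). The call without pairs was lost without any 1 of acetate 2, control 3, acetate 4 and control 5 (0.0566 to 0.290). Of 28 T cell receptor and lineage genes 1 rose and 1 fell (0 adjusted over the list alone; camera adjusted p = 0.240 paired), with Cd8a at a log2 change of -0.04 (adjusted p = 0.767 paired).

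**Figure D3:**
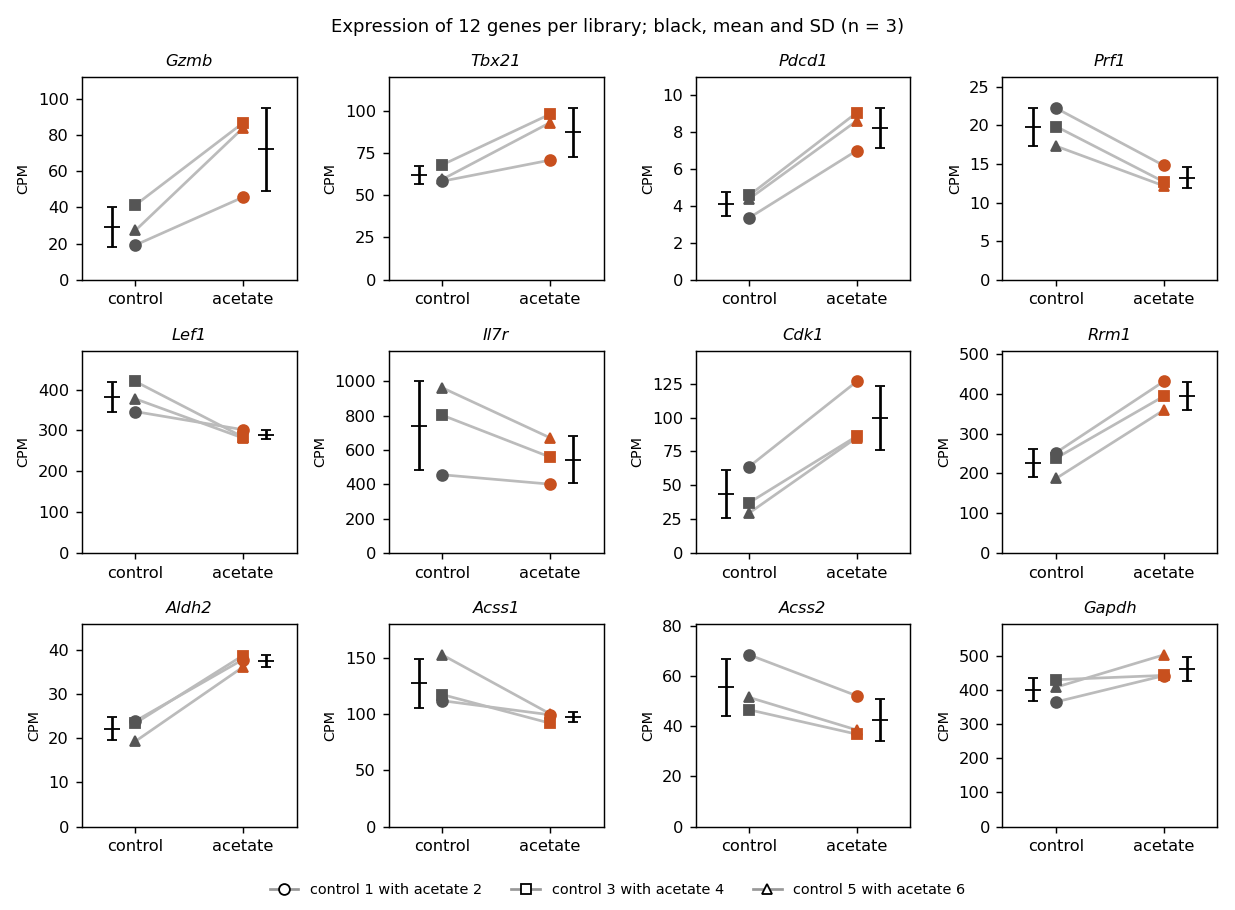
CPM (y axis, from 0) of 12 genes in each library by group (x axis), grey for control and orange for acetate, with lines joining adjacent title numbers and black marks for the mean and SD of each group (n = 3). Gzmb went from a mean of 29.2 to 72.1 CPM and Prf1 from 19.8 to 13.2 CPM, with every pair moving the same way.

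Genes of acetate and acetyl-CoA metabolism changed in both directions, 6 higher and 6 lower of 24 tested (7 and 7 adjusted over the list alone). Acss1, the mitochondrial acetyl-CoA synthetase (chromosome 2, 150618111 to 150668240), went from 127 ± 22.2 to 97.4 ± 4.61 CPM (SD, n = 3; adjusted p = 0.00256 paired, 0.205 without pairs). Acss2, the nuclear and cytosolic enzyme (chromosome 2, 155518043 to 155562743), went from 55.4 ± 11.5 to 42.4 ± 8.38 CPM (SD, n = 3; adjusted p = 0.000169 paired, 0.350 without pairs). Acly, which makes acetyl-CoA from citrate, fell by 0.24, a call lost without either of the pairs control 3 with acetate 4 (adjusted p = 0.155) and control 5 with acetate 6 (0.264). Aldh2, a mitochondrial aldehyde dehydrogenase whose product is acetate, rose 1.70-fold (22.2 ± 2.52 to 37.5 ± 1.33 CPM; SD, n = 3), the acyl-CoA thioesterase gene Acot7 by 0.68 and the carnitine acetyltransferase gene Crat by 0.99 on the log2 scale. The list was not called by camera (adjusted p = 0.654 paired). Of the receptors for short-chain fatty acids, Ffar3 had 0 counts in all 6 libraries and Ffar2 1 count in acetate 4 and 0 elsewhere, so neither was detectable at this depth beyond that count. The monocarboxylate transporter gene Slc16a3 rose by 1.01 and Slc16a1 by 0.19, the latter call lost without control 3 and acetate 4 (adjusted p = 0.226), and 2 of the 7 tested members of that list passed (3 over the list alone; camera adjusted p = 0.240 paired).

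Glycolytic genes were not called as a group (8 of 23 rose and 3 fell, 9 and 4 over the list alone; camera adjusted p = 0.0576 paired). Gapdh (chromosome 6, 125161852 to 125166467) went from 402 ± 33.1 to 464 ± 35.0 CPM (SD, n = 3). Its log2 change of 0.21 lay at the threshold in the paired fit (adjusted p = 0.0498) and did not pass without any 1 of the 3 pairs (0.0784 to 0.300). Eno3 rose by 0.53 and Pfkm by 0.63, while Ldha (0.16) and Hk2 (-0.12) did not pass. Hk2 passed only without control 3 and acetate 4 (adjusted p = 0.0311), in a fit on fewer libraries with a poorly known spread. In the tricarboxylic acid cycle list 4 of 27 genes rose, among them Idh2 (0.36), and 1 fell; over the list alone these were 4 and 0 (camera adjusted p = 0.965 paired). Pdk1, which restrains pyruvate dehydrogenase, fell by 0.24, a call lost without control 3 and acetate 4 (adjusted p = 0.0541) or control 5 and acetate 6 (0.0989).

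Nuclear genes of the respiratory chain rose in 34 of 75 cases and fell in 1 (39 and 3 over the list alone), and cytosolic ribosomal protein genes rose in 25 of 74 with none lower (25 over the list alone). Cox7c rose by 0.42, Ndufc2 by 0.33 and Cox7a2 by 0.29; Rpl35 rose by 0.45, and Rpl31 by 0.32, the latter call lost without control 5 and acetate 6 (adjusted p = 0.0593). Camera called both lists in the paired fit (adjusted p = 0.00016 and 6.92e-07). With an estimated correlation these were at adjusted p = 0.856 and 0.781. Without pairs they were called at 0.00202 and 2.07e-06 (adjusted p = 0.922 and 0.823 with an estimated correlation), but neither was called without acetate 6 (0.567 and 0.0562), nor the respiratory chain list without control 1 (0.138). Short transcripts in general lay higher in acetate: the median log2 change was 0.086 in the fifth of tested genes with the shortest transcripts (median length 739) and -0.103 in the fifth with the longest (4802). The median member of the 2 lists was short (683 and 719), and with the length trend removed the list medians went from 0.18 to 0.11 and from 0.21 to 0.15 (0.04 and 0.08 with a trend fitted to the mean, which also takes away a constant offset). The ribosomal precursor transcript Rn45s took a lower share of counts in acetate in all 3 pairs.

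Lysine acetyltransferases and acetyl-lysine readers fell in 10 of 26 cases and rose in 3 (11 and 3 over the list alone). Kat6b fell by 0.58, Brpf3 by 0.56 and Crebbp by 0.38, while Hat1, which acetylates newly made histone H4, rose by 0.44. Camera called the list lower (adjusted p = 0.0366 paired, 0.0105 without pairs), with adjusted p = 0.690 and 0.644 with an estimated correlation, and the paired call was lost with library totals (0.0505) and without control 5 and acetate 6 (0.0597), and that without pairs was lost without acetate 6 (0.066). Among 18 lysine deacetylases 9 rose, including Hdac1 (0.39) and Hdac6 (0.53), and 3 fell, including Sirt1 (-0.25); the counts over the list alone were the same and camera did not call the list (adjusted p = 0.240 paired).

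Genes of cholesterol synthesis rose in 10 of 24 cases and fell in 1 (12 and 1 over the list alone), with Fdps at 0.48, Mvd at 0.38 and Sqle at 0.33, and the list was not called (camera adjusted p = 0.089 paired). In fatty acid synthesis 3 of 19 genes rose, among them Scd2 (0.54) and Fads1 (0.40), and 3 fell (3 and 3 over the list alone). In fatty acid oxidation 7 of 23 rose, among them Acadl (0.39) and Cpt1a (0.24), and 2 fell (9 and 2 over the list alone). Neither was called (camera adjusted p = 0.986 and 0.392 paired), and for fatty acid synthesis the median and the mean log2 change differed in sign (-0.03 and 0.08).

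**Figure D4:**
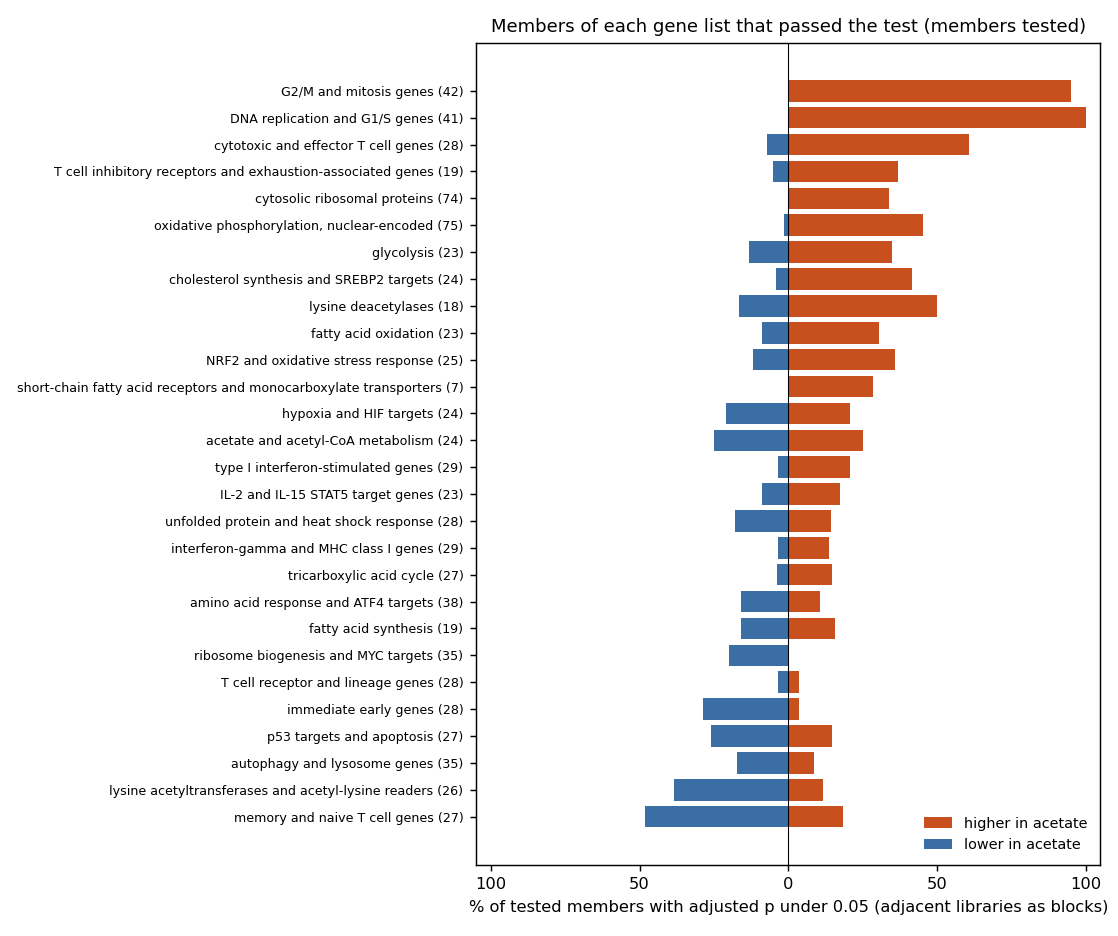
Share of the tested members of 28 gene lists (x axis, percent) with an adjusted p under 0.05 in the paired fit, orange to the right for higher and blue to the left for lower in acetate; the number of tested members follows each name on the y axis. All 41 G1/S genes rose, and the memory and naive list has 13 of 27 members lower.

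The other lists fixed for these cells were not called in the paired fit. Their member counts stand against 2189 higher and 1782 lower among all 12156 tested genes. Ribosome biogenesis genes had 7 of 35 lower and 0 higher (6 over the list alone), with Utp20 down by 0.51 on the log2 scale (camera adjusted p = 0.0576). Immediate early genes had 8 of 28 lower and 1 higher, as over the list alone (0.240). NRF2 and oxidative stress genes had 9 of 25 higher, among them Txn1 (0.59) and Gpx4 (0.37), and 3 lower, as over the list alone (0.240). Hypoxia targets had 5 of 24 in each direction (6 higher and 5 lower over the list alone; 0.857). Amino acid response genes had 4 of 38 higher, among them Mthfd2 (0.45), and 6 lower, as over the list alone (0.242). For unfolded protein and heat shock genes 4 of 28 rose, among them Sdf2l1 (0.68), and 5 fell, as over the list alone (0.857). p53 and apoptosis genes had 4 of 27 higher and 7 lower (5 and 8 over the list alone; 0.345), and autophagy and lysosome genes 3 of 35 and 6 (2 and 5 over the list alone; 0.126). Type I interferon-stimulated genes had 6 of 29 higher, among them Mx1 (0.94) and Isg20 (0.64), and 1 lower (5 and 1 over the list alone; 0.242). Interferon-gamma and MHC class I genes had 4 of 29 higher, among them Psmb9 (0.41), and 1 lower, as over the list alone (0.860).

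Markers of other cell types were mostly at low levels and moved in both directions. Natural killer cell markers, 6 of whose 15 tested members also stand on another list, rose in 7 cases and fell in 1 (8 and 1 over the list alone), with Klrk1, which activated CD8+ T cells also express, up by 0.59 and Klri2 by 1.16 from a low level (mean 1.32 CPM). Camera called that list (adjusted p = 0.00389 paired, 0.690 with an estimated correlation). Dendritic cell and MHC class II markers rose in 7 of 17 cases, as over the list alone, among them H2-DMa (0.47) and Cd83 (0.76); the list was called at an adjusted p = 0.0366 in the paired fit, but at 0.690 with an estimated correlation and at 0.425 without control 3 and acetate 4. Its call without pairs (adjusted p = 0.0466; 0.644 with an estimated correlation) was lost without any 1 of control 1, control 3, acetate 4 and acetate 6 (0.0828 to 0.161). Erythroid and platelet markers, at a median of 0.307 CPM, had 2 of 5 higher (3 over the list alone), among them the transferrin receptor gene Tfrc (0.59). Camera called that list without pairs (adjusted p = 0.047, or 0.474 with an estimated correlation) and not in the paired fit (0.128). B cell markers, at a median of 0.996 CPM, had 3 of 15 higher, among them Cd72 (1.35, at 13.2 CPM) and Cd79b (0.36, a call lost without control 5 and acetate 6 at an adjusted p of 0.0734), and 2 lower (3 and 3 over the list alone), and monocyte and macrophage markers, at a median of 0.819 CPM, 1 of 12 higher and 4 lower, as over the list alone. CD4 and regulatory T cell markers had 2 of 8 higher and stromal and endothelial markers 1 of 13 higher and 3 lower, again as over the list alone. None of these 4 lists was called in the paired fit (adjusted p = 0.439, 0.472, 0.814 and 0.240). Counts of the ribosomal precursor Rn45s were lower in acetate in all 3 pairs, at 0.461 against 0.771% of gene counts, 0.126 against 1.61% and 0.0655 against 0.141%. The share of reads in no gene was also lower in acetate in each pair (7.53 against 8.76%, 8.86 against 9.83% and 7.92 against 8.10%).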

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

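Alternatives of the paired fit were chosen after seeing the data. Without pairs the count of 0 changed genes was the same with median-ratio, upper quartile and library-total scaling, with the stricter filter, with limma-voom, with the fit that is not robust, with a minimum fold of 1.2 and without any 1 library. It was 13 with no filter, 232 at a threshold of 0.1, 789 with DESeq2, 1598 with library quality weights and 3971 with the replicate block; the cause was not tested beyond the pairing tests below. The count of 3971 stayed within 1.5 times under 7 other settings (3232 to 4955), and 3900, 3845 and 3257 of them were called again in the same direction with median-ratio factors, limma-voom and DESeq2. A minimum fold of 1.2 left 1140, and leaving out a pair gave 2484 (without control 5 and acetate 6) to 4400. Of 35 lists, 11 were called without pairs and 10 with pairs, all 10 of them in both. Both counts were 7 with the stricter filter and 0 with an estimated correlation, a test with few degrees of freedom here. Fry called 8 without pairs and 4 with pairs. The 4 that fry called with pairs were the lists of glycolysis, effector genes, G2/M genes and natural killer cell markers. Without pairs, leaving out 1 library gave 7 (without acetate 6) to 10. With pairs, leaving out 1 pair gave 10 (2 lower), 13 (6 lower, without control 3 and acetate 4) and 9 (0 lower, without control 5 and acetate 6). The pair correlations stayed over 0.1 among the 500 most variable genes (lowest 0.254). No named gene and no list reversed direction while called. In edgeR's test with the default filter the replicate block changed the call of every gene said above to rise or fall, and its values stand beside them. Of the camera list calls the block ended only that of erythroid and platelet markers. Counting depth limits only genes near the floor, such as Ifng and Il2.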

Other observations

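Families of genes that share a symbol root, 183 with at least 8 tested members, were scanned with camera in the paired fit after the results above had been seen, and the genes named here were chosen after their values were seen. Of these families 9 were called, and with an estimated correlation none was (adjusted p = 0.861 for each). That test rests on 2 residual degrees of freedom and is adjusted over 183 families, so the lack of calls decides little. A family that was not called, such as Atxn, had the same value. Of 32 histone genes with symbols starting in Hist, 14 rose and 1 fell, with a median log2 change of 1.01 (camera adjusted p = 0.00033). Hist1h2bj rose by 2.12, Hist1h3a by 1.91 and Hist1h3c by 1.96. Reads that aligned to several places were not counted in genes, so counts of these near-identical genes rest on the remaining reads. Most transcripts of these genes are known to lack the poly(A) tail that the kit selects. Of 18 lysine demethylase genes of the Kdm family 11 fell and none rose (median -0.23; camera adjusted p = 0.0131), with Kdm7a down by 0.47, Kdm4b by 0.41 and Kdm5b by 0.29. Vps genes of vesicle sorting had 10 of 31 lower and 1 higher (median -0.12; 0.0289), while mitochondrial ribosomal protein genes (Mrpl) had 18 of 48 higher (0.15; 0.0259) and Haus genes of the mitotic spindle 6 of 8 (0.29; 0.0259). Rpl, Rps, Kif and Mcm genes were also called higher. Of their tested members 40 of 47, 30 of 46, 6 of 28 and 7 of 10 already stand on the fixed lists, so these calls in part repeat those of the lists. Without pairs the Mrpl, Kif and Mcm families were not called (camera adjusted p = 0.0615, 0.208 and 0.086). Directions were the same with median-ratio and library-total scaling. With the transcript length trend removed, the medians were 0.95 for Hist, -0.16 for Kdm, -0.09 for Vps, 0.23 for Haus and 0.11 for Mrpl genes, and went from 0.22 to 0.16 for Rpl and from 0.17 to 0.11 for Rps genes.

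In the 3 patterns that follow, the tests on library depth, on transcript length, on B cells, on monocytes or macrophages and on splits of the gene count without pairs were chosen after the results they measure had been seen. The bootstrap intervals given there resampled the member genes of a list in the paired fit. They measure the spread between genes and not between libraries, and they treat correlated members as independent.

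The first pattern is the dependence of the gene count on blocks. Without blocks edgeR's test called 0 genes (1993 at an unadjusted p under 0.05, and 13 adjusted with no filter), limma-voom 0, DESeq2 789 and library quality weights 1598. Adjacent pairing called 3971 genes with edgeR's test; of the other 5 pairings, that of control 1 with acetate 2, control 3 with acetate 6 and control 5 with acetate 4 called 857 and the others 0. The adjacent pairing was taken because its deviations correlated best in these same libraries, and such blocks leave less spread. Its larger count therefore follows from that correlation. The count is no separate support for adjacent libraries having been handled together, which the labels do not state. Of the 4 splits that part all 3 pairs, only the real one (1 of 4) gave as many genes, the others giving at most 0; 4 splits are too few for a share under 0.05. Without pairs the same count decides nothing, since all 10 splits (at most 0 in the others) reach a real count of 0 by construction. For list calls, 2 of the 4 paired splits gave at least the real 10 (at most 16) and 4 of the 10 splits without pairs at least the real 11 (at most 15). As many list calls thus also arise in some splits that mix the groups. Each mixed split still holds unequal numbers of acetate libraries on its sides, so none of them is free of acetate.

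The second pattern is the higher level of mitosis genes in acetate in every pair (median 1.08). The acetate library was the deeper one in 1 of the 3 pairs, which argues against a difference in library depth. Removing the length trend left a median of 1.11 (95% bootstrap interval over the genes of the list from 1.03), which argues against length in these libraries. Markers of B cells had a median change of -0.34 and those of monocytes or macrophages -0.034, with intervals that end at 0.205 and 0.213, which argues against carried-over splenocytes of these kinds as the whole cause. Of single markers, chosen after their values were seen, Pou2af1 (15.0 CPM) and Cd72 (13.2 CPM) went the other way and rose by 0.41 and 1.35, while Cd79a and Ms4a1 lay at 1.15 and 1.82 CPM with log2 changes of -0.48 and -0.36 that did not pass, and Ctss (154 CPM) fell by 0.19. By pair the mean differences were -0.32, 0.18 and -0.30 for B cell markers and -0.26, 0.15 and -0.12 for those of monocytes or macrophages. In control 3 and acetate 4 both thus moved the way of the mitosis genes, though by less than their 0.98. The share of dividing cells, culture time within the stated 3 to 4 days and carry-over of natural killer or dendritic cells, whose markers lay higher in acetate, stay open and were not tested.

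The third pattern is the set of lists whose members differ in transcript length. For ribosomal protein genes the median change went from 0.21 to 0.15 (interval 0.115 to 0.166) and for effector genes from 0.45 to 0.45 (0.337 to 0.551) when the length trend of genes outside the lists was removed, which argues against length as the whole cause for these. For respiratory chain genes it went from 0.18 to 0.11 (0.0783 to 0.146), for memory genes from -0.20 to -0.14 (-0.224 to -0.0587) and for acetyltransferases from -0.076 to -0.087 (-0.178 to 0.0422), intervals too wide to place these above or below 0.5 of the change before. A trend fitted to the mean, which also takes away a constant offset, left 0.04 for respiratory chain and 0.08 for ribosomal protein genes, each under 0.5 of the change before, 0.38 for effector, -0.22 for memory and -0.15 for acetyltransferase genes, so for ribosomal protein genes the reading rests on the centred trend. What made short transcripts higher, such as RNA integrity, library preparation or acetate itself, was not tested; Rn45s was also lower in acetate in all 3 pairs.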
